A study of Danio rerio with 14 samples.

How the data were processed

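Messenger RNA of single cells was measured in 14 libraries of zebrafish ventricle, 7 from wild type fish and 7 from kit mutant fish, which carried alleles of both kita and kitb per the labels. Hearts were uninjured or had lost part of the ventricular apex 2, 7 or 14 days earlier (days post injury, dpi). Per the labels, cardiomyocytes were separated from the other cells by repeated centrifugation, and the other cells were loaded on a droplet instrument (10x Chromium, version 2 chemistry). The deposited tables hold counts of unique molecular identifiers (UMIs) per gene and cell, 1 table per genotype, with 35117 genes. Per the submitters' processing notes, Cell Ranger 2.0.2, FastQC and the zebrafish build danRer10 were used. How cells were chosen among barcodes is not given in the sources used here. The tables hold 38181 barcodes of wild type and 49133 of kit mutant, 87314 in all.

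Groups of genotype and time were taken from the sample titles and descriptions, which gave 6 groups of 2 libraries. The wild type group at 14 dpi and the uninjured kit mutant group held 1 library each. For 3 kit mutant libraries the source name and characteristics give an earlier time than the title: replicate 1 at 2 dpi is called uninjured there, replicate 1 at 7 dpi is called 2 dpi and replicate 1 at 14 dpi is called 7 dpi. Grouping by those labels and leaving the 3 libraries out were run as alternatives. Nothing in the labels says how many fish each library came from, so p-values measure the spread between these libraries, which may in part be technical.

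Library totals ranged from 9654139 to 48344216 UMIs over 1167 to 15209 barcodes. Cells were kept with at least 500 UMIs, at least 200 detected genes and at most 20% of UMIs from mitochondrial genes. The share of barcodes that passed was 32.63% in kit mutant 2 dpi replicate 2, 42.92% in wild type uninjured replicate 1 and 47.13% in wild type uninjured replicate 2, the 3 lowest of the 14 libraries. Cells with the highest Scrublet scores were removed as doublets at a rate of 0.8% per 1000 cells. In all, 54860 cells were kept, 1152 to 9932 per library, with a median of 2738.5 to 7900 UMIs per cell and library. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 40 principal components and 15 neighbours gave 34 Leiden clusters at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). A cluster was named after a cell type when at least 3 of that type's markers set it apart, with a mean log2 fold of at least 1.5 over the markers and a lead of 0.5 over the next type. Of the clusters, 27 were named, and 3553 cells (6.48%) lay in unnamed clusters. Class names such as endothelial-like rest on these markers alone.

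UMIs were summed over the cells of a class within each library, so that the library and not the cell was the unit. Libraries with fewer than 20 cells of a class were left out of that class. Each class was fitted with edgeR 4.0.16 (R 4.3.3) with TMM normalization, its filterByExpr filter and 1 coefficient for each of the 8 groups, which left 6 residual degrees of freedom. The 5 comparisons were wild type at 2, 7 and 14 dpi against uninjured, kit mutant against wild type averaged over the 4 time points, and the interaction of genotype and time with 3 degrees of freedom. All adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of a class and comparison, with a threshold of 0.05. Groups of 1 library were assumed to vary as the other groups. The fitted log2 changes are given with their standard error (SE). Where every library of a group had 0 UMIs, the fold is a lower bound against 3 UMIs over the group. Where a group had 1 to 3 UMIs, the ratio of pooled counts is given with its 95% counting interval. These intervals and bounds cover counting error only.

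The 19 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, on log2 CPM (counts of a gene per fixed library total, as edgeR computes them) with a prior count of 2. List counts are also given after adjustment over the list alone. Shares of cell classes were tested with the same edgeR model on cell numbers per library. Beside it stand exact two-sided permutation tests of genotype within time points (324 splits, smallest p possible 0.00309) and of injury within genotype (147 splits, smallest p possible 0.0068). Intervals of single shares are exact 95% binomial intervals (Clopper-Pearson).

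Named genes followed a rule. It took, per class and comparison, up to 8 genes with the largest rise and up to 8 with the largest fall past the threshold, with a mean of at least 20 CPM. Their values had to lie apart between the compared groups or, for genotype, differ with the same sign at all 4 time points. Genes named only by a clone or database identifier, mitochondrial, ribosomal protein and haemoglobin genes and markers of other classes were left out. Up to 3 called members of each list and the genes kita, kitb, kitlga and kitlgb were added. Not every gene that this rule names is reported. This rule, the groups, gene lists, markers, tests and most alternatives were chosen before the data were examined.

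The workflow was tested on simulated data with 200 changed genes per class and comparison. In the genotype comparison, 85.9% of genes changed by a log2 of 2 were recovered in endothelial-like cells, 79.4% in fibroblast- or epicardial-like cells and 79% in macrophage-like cells. In wild type at 2 dpi the corresponding values were 11.3%, 7.7% and 1.7%, and at a log2 of 4 they were 76.2%, 89.4% and 67.3%. A smaller change was therefore mostly missed in the comparisons of single time points. Of the genes called in the simulated data, the share that had not been changed was often above the nominal 5%. In the same order of classes it was 6.1%, 8.1% and 3.6% for genotype and 6.7%, 7.2% and 7.3% at 2 dpi. It was 1.9%, 13.8% and 4% at 7 dpi, 0%, 5.1% and 4.2% at 14 dpi and 11.8%, 13.5% and 25% for the interaction. Each share comes from 1 simulated data set, those of the interaction from 17, 52 and 4 called genes. The simulated libraries were drawn independently, without structure shared between libraries. Recovery and false calls in the real data may therefore differ.

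The alternatives chosen at that stage were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, both other treatments of the 3 libraries whose labels differ, the replicate number as a block, doublets kept, a stricter cell filter (1000 UMIs and 500 genes), Leiden resolution 0.5, another total for shares, an estimated correlation for lists and each library left out in turn. A mitochondrial limit of 40% and covariates for 2 sets of libraries that stood apart were chosen after seeing the data. The first set was found in endothelial-like cells and entered in every class, and the second was found in fibroblast- or epicardial-like cells and entered there.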

Results

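The series examined how non-myocyte cells of the zebrafish heart respond at successive times after resection of the ventricular apex, in wild type and in kit mutant fish. Single-cell counts were available for 14 libraries. Wild type was represented by 2 libraries each for uninjured hearts, 2 dpi and 7 dpi and by 1 library at 14 dpi. Kit mutant was represented by 1 uninjured library and 2 libraries each at 2, 7 and 14 dpi. The 54860 cells kept held endothelial-like, fibroblast- or epicardial-like and macrophage-like cells as the classes followed through every library. Totals per library ranged from 9654139 to 48344216 UMIs. Macrophage-like cells numbered 39 and 346 in the wild type uninjured libraries and 97 and 3840 in those at 2 dpi.

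The mutated genes were almost absent from the counts of either genotype. In endothelial-like cells kita, which encodes a receptor tyrosine kinase, had 1 UMI in kit mutant and 1 in wild type libraries, and its paralog kitb had 0 in both. For kitb this allows at most 0.0597 CPM in kit mutant and 0.103 CPM in wild type endothelial-like cells. The ligand gene kitlga was detected, with 393 UMIs in kit mutant and 231 in wild type endothelial-like cells, and its difference there was 0.01 ± 0.33 (log2, SE, 7 libraries against 7). In macrophage-like cells kitlga stood at 11.3 CPM in kit mutant and 21.2 CPM in wild type, with a difference of -0.62 ± 0.55 that was not past the threshold (adjusted p = 0.722) and had the opposite sign (1.22) without wild type uninjured replicate 2. The pooled wild type value came mostly from 2 dpi, with 426 of 493 UMIs (27.4 CPM against 7.58 in uninjured hearts, 10.3 at 7 dpi and 2.06 at 14 dpi). At this depth kita and kitb could not be used to check the genotype labels.

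The first comparison asked which genes changed in wild type hearts 2 days after resection. In fibroblast- or epicardial-like cells the genes that rose included many of cell division and single genes of matrix. Genes for collagen XII, a collagen that binds the surface of other fibrils, rose 85.5-fold (col12a1b, log2 6.42 ± 0.83 SE, adjusted p = 0.00183) and 25.6-fold (col12a1a, 4.68 ± 0.64, adjusted p = 0.00201), with 2 libraries against 2. The gene timp2b, which encodes an inhibitor of matrix metalloproteinases, rose 18.7-fold (4.23 ± 0.48, adjusted p = 0.000916). The growth factor gene mdka rose 6.25-fold to a mean of 6390 CPM, while its paralog mdkb fell 17.2-fold (adjusted p = 0.00332) to 22.3 CPM. The tetraspanin gene cd9b rose 26.8-fold, but its pooled level at 2 dpi was lower here (99.6 CPM) than in macrophage-like cells (547 CPM). Fibronectin (fn1a), an adhesive matrix protein, rose 16.9-fold (adjusted p = 0.00201).

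Genes that fell in these cells included rbp4, which encodes the carrier of retinol, from a mean of 11400 to 941 CPM (fall of 12.1-fold, adjusted p = 0.00183). The signalling ligand gene bmp4 fell by 4.00 ± 0.60 and igfbp2a, whose product binds insulin-like growth factors, fell by 5.63 ± 0.91 (log2). The claudin gene cldn7a, a component of tight junctions, fell by 7.93 ± 0.87. The lipocalin genes ptgdsb.1 and ptgdsb.2, related to prostaglandin D synthase, fell too, ptgdsb.1 fell by 6.22 ± 0.69 and ptgdsb.2 fell by 9.39 ± 0.75 to 4 UMIs against 493 in uninjured hearts. The fatty acid binding protein gene fabp10a had 1 UMI at 2 dpi and 187 in uninjured hearts (ratio 0.00108, counting interval 2.72e-05 to 0.00608). Each gene of these paragraphs kept both 2 dpi libraries on 1 side of both uninjured libraries.

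Of the 40 tested members of the cell cycle list, 27 rose and none fell over all genes, and 35 rose and 1 fell adjusted over the list alone. Their median log2 change was 3.75, or 3.49 with genes at 0 placed at their bound (camera adjusted p = 1.56e-26; adjusted p = 0.387 with an estimated correlation). The importin gene kpna2 and the mitotic ubiquitin-conjugating enzyme gene ube2c had 0 UMIs in uninjured hearts and were at least 97.6-fold and at least 73.6-fold higher at 2 dpi, with 1453 and 1096 UMIs. The survivin gene birc5a had 2 UMIs in uninjured and 475 in 2 dpi libraries (ratio 47.9, counting interval 13.2 to 397). Of 49 members of the fibrillar matrix list 6 rose over all genes, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.365). Of 22 matrix proteases and inhibitors 3 rose and 1 fell over all genes, and 3 rose and 5 fell adjusted over the list alone (median 0.32, or 0.07 with bounds, camera adjusted p = 0.828). Of 48 genes of oxidative phosphorylation 7 rose, and 27 rose adjusted over the list alone (median 1.11, camera adjusted p = 3.6e-09; adjusted p = 0.571 with an estimated correlation), among them the cytochrome c oxidase subunit genes cox7a2a (5.64-fold) and cox6b1 (6.71-fold). Inflammatory cytokine and chemokine genes had 2 of 23 members higher and 7 adjusted over the list alone (median 1.48, camera adjusted p = 0.0276; adjusted p = 0.387 with an estimated correlation). Mitochondrial genes took 11.4% ± 0.932 (SD, n = 2) of the UMIs of these cells in uninjured hearts and 2.58% ± 2.76 at 2 dpi. Macrophage markers in these cells had a median change of 1.61, with 0 of 10 called higher and 1 lower. Endothelial markers had a median of -2.19 with 2 of 12 called lower, mural markers of -1 with 2 of 7 called lower, and cardiomyocyte markers of -1.32 with 1 of 11 called lower. At 2 dpi 58.1% of the class in wild type lay in cluster 10, which held 1 cell (0.1%) of the class in uninjured wild type and 49.6% in kit mutant at 2 dpi, so the compared groups differ in the clusters they draw on.

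In total 495 of 11648 genes were called in fibroblast- or epicardial-like cells at 2 dpi, 272 higher and 223 lower. The count was 44 without wild type uninjured replicate 1, 198 without wild type uninjured replicate 2, 93 without wild type 2 dpi replicate 1, and 845 and 768 without kit mutant 2 dpi replicate 1 and 2; fn1a, cox7a2a and cox6b1 were past the threshold in each of these fits but that without wild type uninjured replicate 1 (adjusted p = 0.0584, 0.111 and 0.119). With the 3 kit mutant libraries grouped by their other labels, which leaves the wild type groups as they are and changes the shared estimate of spread, edgeR called 0 genes, with an adjusted p of 0.229 for col12a1a, timp2b, mdka and rbp4. On a scale from uninjured to 2 dpi wild type set by the 495 genes, kit mutant 2 dpi replicate 1, which its other labels call uninjured, lay at 101.3%, and kit mutant 7 dpi replicate 1, which they call 2 dpi, at 28.4%; the uninjured kit mutant library lay at 8.4% and kit mutant 2 dpi replicate 2 at 80.9%.

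**Figure D1:**
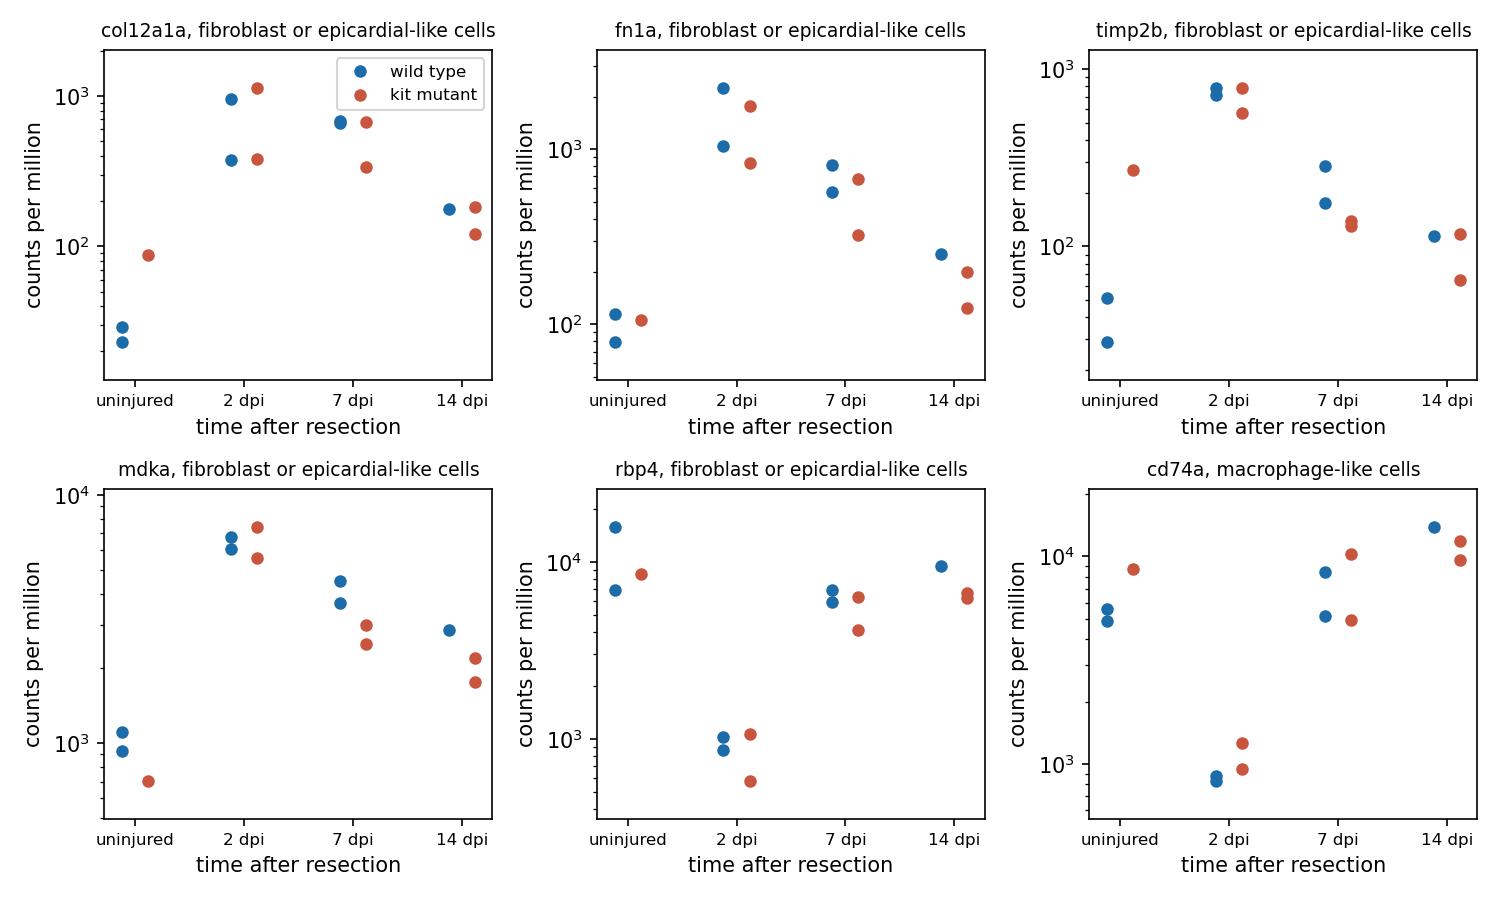
CPM (log axis) of col12a1a, fn1a, timp2b, mdka and rbp4 in fibroblast- or epicardial-like cells and of cd74a in macrophage-like cells, against time after resection; each point is 1 library of wild type (blue) or kit mutant (red). The mean of mdka in wild type was 1020 CPM in uninjured hearts and 6390 CPM at 2 dpi, and that of rbp4 11400 and 941 CPM.

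At 7 dpi some matrix genes of fibroblast- or epicardial-like cells were higher than in uninjured hearts. The collagen genes col12a1b and col12a1a rose 48.5-fold (log2 5.60 ± 0.81 SE) and 25.7-fold (4.68 ± 0.64, both adjusted p = 0.033, 2 libraries against 2). Periostin (postnb), a matrix protein of fibroblasts, rose 5.63-fold to 1780 CPM (adjusted p = 0.0487), while timp2b rose 5.72-fold and mdka 3.98-fold. The lipocalin gene ptgdsb.2 fell by 2.86 ± 0.51 (log2, adjusted p = 0.0487). For each of these genes both 7 dpi libraries lay on 1 side of both uninjured libraries. The fibrillar matrix list had 4 of 49 members higher and 8 adjusted over the list alone, with a median of 0.73, or 0.64 with bounds (camera adjusted p = 2.52e-06; adjusted p = 0.35 with an estimated correlation). The cell cycle list had no member past the threshold, and its median was 1.79, or 0.84 with bounds (camera adjusted p = 3.06e-10; adjusted p = 0.336 with an estimated correlation). Macrophage markers had a median of 1.48 in these cells (0.9 to 6.92, 0 of 10 called). Mitochondrial genes took 4.93% ± 4.2 (SD, n = 2) of their UMIs against 11.4% in uninjured hearts, and cluster 10 held 14.6% of the class against 0.1%. In all 14 of 11648 genes were called, 13 higher. None was called without wild type 7 dpi replicate 1 or without either uninjured wild type library, and the count was 7, 8, 3 and 3 without kit mutant 14 dpi replicate 1 and 2 and 7 dpi replicate 1 and 2. The count was 0 with the other grouping of the 3 kit mutant libraries, 2 without these libraries, 7 with doublets kept, 7 with Leiden resolution 0.5 and 4 with a mitochondrial limit of 40%, an alternative chosen after seeing the data.

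At 14 dpi, with 1 wild type library against 2, col12a1a stood at 177 CPM and postnb at 1140 CPM in fibroblast- or epicardial-like cells, against 26.1 and 315 CPM in uninjured hearts. No gene was past edgeR's threshold there, 386 genes had an unadjusted p under 0.05, and DESeq2 called 2. Antigen presentation genes had a median of 1.09 (camera adjusted p = 0.00132; adjusted p = 0.308 with an estimated correlation), with 2 of 16 higher adjusted over the list alone. Interferon response genes had a median of 0.86, or 0.61 with bounds (camera adjusted p = 0.000916; adjusted p = 0.416 with an estimated correlation), with 0 of 17 past the threshold. Macrophage markers had a median of 1.61 in these cells (0.9 to 7.04, 0 of 10 called), mitochondrial genes took 5.3% of their UMIs (n = 1) and cluster 10 held 7.4% of the class.

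In macrophage-like cells of wild type at 2 dpi the genes that rose included some of lipid transport and storage, and the genes named here were not past the threshold without either of the uninjured libraries. The gene fabp11a, which encodes a fatty acid binding protein, rose 18.1-fold (log2 4.18 ± 0.63 SE, adjusted p = 0.0274, 2 libraries against 2) to a mean of 14000 CPM. The gene g0s2, whose product inhibits the lipase of lipid droplets, rose 92.1-fold (adjusted p = 0.0274). The apolipoprotein genes apoc1 and apoeb had 0 and 1 UMI in uninjured libraries. At 2 dpi apoc1 was at least 72.4-fold higher, and apoeb had 6599 UMIs (ratio 559, counting interval 100 to 22100). The tetraspanin gene cd9b rose 27.9-fold, and jac3 and jac9 went from 2 and 1 UMIs to 50839 and 45125 (ratios 2150 and 3820, counting intervals 596 to 17800 and 686 to 151000). The gene cd74a, which encodes the invariant chain of class II antigen presentation, fell 6.12-fold (adjusted p = 0.0338), from 5240 to 855 CPM. The lipid handling list had 3 of 13 members higher and 6 adjusted over the list alone (median 1.11, camera adjusted p = 5.74e-06; adjusted p = 0.266 with an estimated correlation). Phagolysosome genes had 1 of 28 higher and 9 adjusted over the list alone (median 0.93, camera adjusted p = 0.000162; adjusted p = 0.686 with an estimated correlation).

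The macrophage-like cells of 2 dpi came in part from clusters that were scarce at other times, 1 of which held 26.3% of the class in wild type and 25.5% in kit mutant at 2 dpi and another 24.1% in wild type and 6.2% in kit mutant; 85.9% of the cells of the latter cluster came from wild type 2 dpi replicate 2. Mitochondrial genes took 12.1% ± 1.9 (SD, n = 2) of the UMIs of the class in uninjured wild type hearts and 4.45% ± 4.72 at 2 dpi. Endothelial markers had a median of -2.04 in these cells (-2.76 to -0.46, 0 of 11 called) and fibroblast or epicardial markers of 0.96 (-0.82 to 7.72, 0 of 11 called). In all 10 of 7690 genes were called, 9 higher, and for each of those given here both 2 dpi libraries lay on 1 side of both uninjured libraries. The count was 0 without wild type uninjured replicate 1 (39 cells), without wild type uninjured replicate 2 and with the other grouping of the 3 kit mutant libraries; it was 1 and 21 without wild type 2 dpi replicate 1 and 2, 6 without kit mutant 7 dpi replicate 1, and 19 without wild type 7 dpi replicate 1 or 2. At 7 and 14 dpi edgeR called 0 genes, with 136 and 238 at an unadjusted p under 0.05, and DESeq2 also called 0. Without the filter on low counts edgeR did call genes at both times. The mean of fabp11a was 491 CPM at 7 dpi and 204 CPM at 14 dpi, and that of cd74a 6810 and 13900 CPM.

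In endothelial-like cells of wild type no gene was past the threshold at any time after injury. At 2 dpi, 504 of 13329 genes had an unadjusted p under 0.05 and DESeq2 called 42, at 7 dpi the counts were 307 and 4, and at 14 dpi 261 and 0. At the preset correlation 12, 10 and 5 of the 19 gene lists passed the threshold at 2, 7 and 14 dpi. Cell cycle genes had a median log2 change of 1.40 at 2 dpi, with 0 of 38 past the threshold and 9 higher adjusted over the list alone (camera adjusted p = 2e-17; adjusted p = 0.206 with an estimated correlation). Inflammatory cytokine and chemokine genes had a median of 1.38 at 2 dpi, with 6 of 28 higher adjusted over the list alone (camera adjusted p = 7.82e-11; adjusted p = 0.201 with an estimated correlation). At 7 dpi their median was 1.43, or 1.37 with bounds, with 1 of 28 higher adjusted over the list alone (camera adjusted p = 3.09e-12; adjusted p = 0.21 with an estimated correlation). Notch signalling genes had a median of -0.54 at 2 dpi (camera adjusted p = 0.00467; adjusted p = 0.421 with an estimated correlation), with 0 of 22 past the threshold. Macrophage markers in these cells had a median of 1.5 at 2 dpi and 1.57 at 7 dpi, with 0 of 12 called at either time. Mitochondrial genes took 10.9% ± 1.06 (SD, n = 2) of their UMIs in uninjured hearts and 3.35% ± 3.74 at 2 dpi. Immediate early and heat shock genes, which dissociation of tissue can induce, had a median of 0.19 at 2 dpi (camera adjusted p = 0.00467; adjusted p = 0.61 with an estimated correlation) and 0.47 at 7 dpi (camera adjusted p = 2.68e-06; adjusted p = 0.402 with an estimated correlation). They took 1.021% and 6.322% of the UMIs of the 2 uninjured libraries, and without wild type uninjured replicate 1 the list had the opposite direction at 2 dpi (adjusted p = 0.00701) and at 7 dpi (adjusted p = 0.435). Without wild type 2 dpi replicate 1 or 2, edgeR called 1 and 5 genes at 2 dpi. No list of the 3 classes held its call with an estimated correlation in any comparison, the lowest adjusted p being 0.123.

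The comparison of genotypes asked which genes differed between kit mutant and wild type over all times, with 7 libraries against 7. In endothelial-like cells the coagulation factor genes f10 and F7 (1 of many) were 3.27-fold (log2 1.71 ± 0.25 SE, adjusted p = 0.00457) and 5.84-fold (2.55 ± 0.45, adjusted p = 0.013) higher in kit mutant. The gene spint2, which encodes an inhibitor of serine proteases, fell by 2.92 ± 0.36 (log2, adjusted p = 0.00236) in kit mutant, and ctsba, which encodes the lysosomal protease cathepsin B, by 1.59 ± 0.23 (adjusted p = 0.00444). The antiviral gene rsad2 was 14.4-fold lower (adjusted p = 0.0174) and the tetraspanin gene cd81b 3.70-fold lower (adjusted p = 0.00284). The nuclease gene dnase1l4.1 had 4 UMIs in kit mutant and 1921 in wild type (-9.70 ± 0.69, adjusted p = 3.27e-05), and its neighbour in name dnase1l4.2 was 10.1-fold lower. Each of these genes differed with the same sign at all 4 time points.

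Interferon response genes in endothelial-like cells had 2 of 19 members lower in kit mutant and 6 adjusted over the list alone (median -0.78, camera adjusted p = 0.0028; adjusted p = 0.637 with an estimated correlation). Glycolysis and hypoxia genes had 1 of 30 higher and 3 adjusted over the list alone (median 0.33, camera adjusted p = 0.00293; adjusted p = 0.449 with an estimated correlation). Macrophage markers in these cells had a median of -1.68, with 2 of 12 called lower, T or NK markers of -1.67, with 0 of 4 called, and fibroblast or epicardial markers of -0.08, with 1 of 13 called lower. The lists of complement, cell cycle and phagolysosome genes had medians of -1.05, -0.20 and -0.28 (each camera adjusted p = 0.0429; adjusted p = 0.449, 0.753 and 0.659 with an estimated correlation). Different clusters held most of the class in each genotype, numbers 1 and 2 in kit mutant and 5 and 6 in wild type. In all 349 of 13329 genes were called, 148 higher and 201 lower, and 221 of them were also called with a set of libraries as a covariate, an alternative chosen after seeing the data. The count was 202, 185, 134, 211 and 198 without kit mutant 14 dpi replicate 2, kit mutant 7 dpi replicate 1, kit mutant 7 dpi replicate 2, wild type 7 dpi replicate 1 and wild type uninjured replicate 2, and the comparison could not be fitted without the only library of a group. Of the called genes 46.4% had only a clone or database identifier, against 19.6% of the genes tested.

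In fibroblast- or epicardial-like cells fah, which encodes the last enzyme of tyrosine breakdown, was 7.50-fold higher in kit mutant (log2 2.91 ± 0.33 SE, adjusted p = 0.00176, 7 libraries against 7). The receptor gene notch3, which is also among the mural markers, was 3.74-fold higher (adjusted p = 0.00867), the peptidase gene mmel1 3.50-fold (adjusted p = 0.00838) and the glucagon gene gcga 4.44-fold (adjusted p = 0.0167). The ubiquitin-like modifier gene isg15, induced by interferon, was 6.39-fold lower (adjusted p = 0.00907), and gig2d 5.37-fold lower (adjusted p = 0.00279). As in endothelial-like cells, ctsba fell, by 1.97 ± 0.27 (log2, adjusted p = 0.00279). The filamin-binding gene fblim1 was 3.63-fold lower and mustn1a 5.56-fold lower. Each difference had the same sign at all 4 time points.

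The interferon response list had 3 of 17 members lower in these cells and 8 adjusted over the list alone (median -0.79, camera adjusted p = 7.62e-06; adjusted p = 0.39 with an estimated correlation). Antigen presentation genes had 2 of 16 lower and 8 adjusted over the list alone (median -0.66, camera adjusted p = 0.000251; adjusted p = 0.246 with an estimated correlation), and phagolysosome genes 1 of 25 and 3 (median -0.43, camera adjusted p = 0.000155; adjusted p = 0.246 with an estimated correlation). Members of the kit pathway list had a median of 0.41 (camera adjusted p = 0.0293; adjusted p = 0.39 with an estimated correlation), with 0 of 10 past the threshold. Macrophage markers in these cells had a median of -1.39, with 3 of 10 called lower, mural markers of 1.1, with 1 of 7 called higher, neural or Schwann markers of 1.86, with 1 of 4 called higher, and T or NK markers of -2.25, with 0 of 7 called. Cluster 3 held 58.1% of the class in kit mutant and 53.4% in wild type in uninjured hearts, and 32.2% and 32.8% at 2 dpi. At 7 dpi it held 53.9% and 34.4%, and at 14 dpi 53.2% and 34.1%. Mitochondrial genes took 5.77% of the UMIs in kit mutant and 11.4% in wild type in uninjured hearts, and 5.59% and 2.58% at 2 dpi. Their means at 7 dpi were 9.08% and 4.93%, and at 14 dpi 7.03% and 5.3%. In all 260 of 11648 genes were called, 121 higher. With a set of libraries found in this class as a covariate, chosen after seeing the data, 85 of them were also called, and notch3 and isg15 had an adjusted p of 0.0502 and 0.0543. The count was 129 without kit mutant 14 dpi replicate 2, 56.5% of the 260 without kit mutant 2 dpi replicate 2, 153 and 114 without kit mutant 7 dpi replicate 1 and 2, and 137 without wild type uninjured replicate 2. With the other grouping of the 3 kit mutant libraries it was 111, and the adjusted p of notch3, mmel1, gcga and fblim1 was then 0.0832, 0.0853, 0.0546 and 0.0634.

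In macrophage-like cells the class II antigen presentation gene mhc2dab was 3.04-fold higher in kit mutant (log2 1.60 ± 0.26 SE, adjusted p = 0.0148), and ralgps1, which encodes an activator of Ral GTPases, 18.4-fold (4.21 ± 0.56, adjusted p = 0.00452), each with the same sign at all 4 time points and 7 libraries against 7. Of 15 antigen presentation genes mhc2dab was the 1 past the threshold (list median 0.30, camera adjusted p = 0.199). The naming rule leaves out genes with only a clone or database identifier. Among these, a run of 3 neighbours on chromosome 8 was lower in kit mutant. Its log2 differences were -6.43 (zgc:103700, adjusted p = 0.000128), -10.86 (adjusted p = 0.000201) and -11.29 (adjusted p = 9.87e-05). The gene zgc:103700 was among the top genes of cluster 4 and mhc2dab among those of cluster 7. Whether this run is tied to mhc2dab was not tested. Genes of oxidative phosphorylation had a median of -0.26 (camera adjusted p = 0.00334; adjusted p = 0.92 with an estimated correlation), with 0 of 48 past the threshold. Mitochondrial genes took a mean over 1 or 2 libraries of 8.24% of the UMIs of the class in kit mutant and 12.1% in wild type in uninjured hearts, 9.06% and 4.45% at 2 dpi, 12.4% and 7.85% at 7 dpi and 9.1% and 8.45% at 14 dpi. Thrombocyte markers had a median of 0.68 (0.39 to 1.33, 0 of 5 called), erythrocyte markers of 0.65 (-2.04 to 1.35, 0 of 9 called) and mural markers of -1.78 (-3.98 to 1.92, 0 of 4 called). Most of the class lay in different clusters in the genotypes, cluster 4 holding 89.1% of it in uninjured wild type and cluster 7 holding 90.4% in uninjured kit mutant. In all 54 of 7690 genes were called, 21 higher, and 29 of them were also called with the set of libraries as a covariate. The count was 20, 23, 22, 23, 31 and 23 without kit mutant 14 dpi replicate 2, 2 dpi replicate 2, 7 dpi replicate 1, 7 dpi replicate 2, wild type uninjured replicate 1 and wild type uninjured replicate 2, and mhc2dab had an adjusted p of 0.0732 with the other grouping of the 3 kit mutant libraries.

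The 3 classes shared genes of the genotype comparison. Of genes tested in both, 43 were called higher and 71 lower in endothelial-like and in fibroblast- or epicardial-like cells, where independent lists would share 1.1 and 1.9. The classes come from the same libraries, so the lists are not independent. In all 3 classes 21 genes were called, each with the same sign, 8 higher and 13 lower. Of those lower, zgc:123068, si:dkey-188i13.6, zgc:152791, si:dkey-188i13.7 and si:dkey-188i13.9 lie in 1 run of neighbours on chromosome 13. The 21 genes are therefore not 21 separate places in the genome. Among the 21 genes fah was higher by 5.46, 2.91 and 4.28 (log2) in endothelial-like, fibroblast- or epicardial-like and macrophage-like cells. The gene stat3, which encodes a transcription factor of cytokine signalling, was higher by 1.46, 1.78 and 1.71 in the same order. With the set of libraries as a covariate stat3 had a difference of 1.41 in macrophage-like cells (adjusted p = 0.0668). The splicing gene snu13a had differences of -2.48, -2.38 and -4.78 in the same order. These genes were picked from the shared set after their values were seen.

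**Figure D2:**
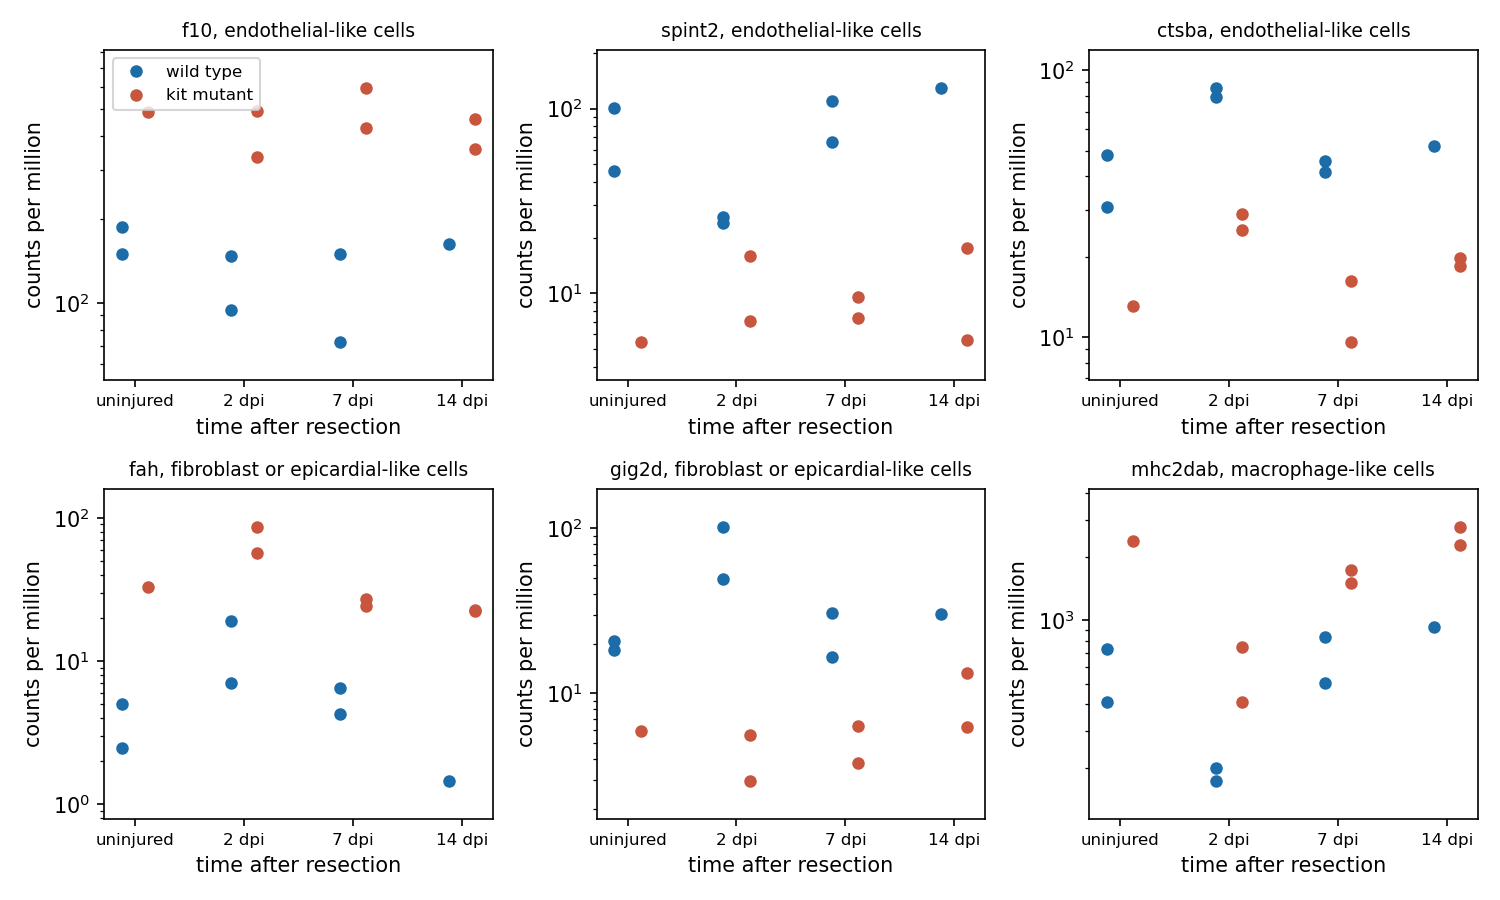
CPM (log axis) of f10, spint2 and ctsba in endothelial-like, fah and gig2d in fibroblast- or epicardial-like and mhc2dab in macrophage-like cells, against time after resection; each point is 1 library of wild type (blue) or kit mutant (red). The mean of f10 was 169 CPM in uninjured wild type and 487 CPM in uninjured kit mutant, and that of mhc2dab 573 and 2380 CPM.

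The last comparison of genes asked whether the difference between genotypes varied with time. The interaction test called 0 genes in endothelial-like, fibroblast- or epicardial-like and macrophage-like cells, with 83, 95 and 46 genes at an unadjusted p under 0.05, and DESeq2 called 8, 3 and 0. In fibroblast- or epicardial-like cells the mean of col12a1a at 2 dpi was 667 CPM in wild type and 754 CPM in kit mutant, and that of mdka 6390 and 6490 CPM. In macrophage-like cells the mean of jac3 at 2 dpi was 9470 CPM in wild type and 302 CPM in kit mutant, and that of fabp11a 14000 and 2780 CPM, without a difference past the threshold of this test. Pooled over the wild type libraries, of 97 and 3840 cells, jac3 stood at 3270 CPM, so the smaller library raises its mean. Without wild type 2 dpi replicate 2, edgeR called 2 genes in fibroblast- or epicardial-like cells. In simulated data the test recovered 0%, 7.7% and 0% of genes changed by a log2 of 2 and 23.4%, 60.6% and 4.8% of those changed by a log2 of 4 in the 3 classes, in the same order.

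Shares of cell classes are shares of the cells loaded after centrifugation had removed cardiomyocytes. They also depend on the mitochondrial filter and on the minimum of detected genes. Cells of the erythrocyte-like cluster 11 had a median of 261 genes. Barcodes below the minimum of UMIs or genes numbered 1231 of 4089 and 244 of 7012 in uninjured wild type replicates 1 and 2. At 2 dpi they numbered 4 of 1167 and 97 of 11759, and at 7 dpi 28 of 2190 and 234 of 7759. All had at least 956 UMIs, so they fell short on genes. How many were erythrocytes, and how far this changed the shares below, was not tested. Erythrocyte-like cells were 1.16% ± 0.25 (SD, n = 2) of cells in uninjured wild type hearts and 4.43% ± 0.741 at 2 dpi (log2 change 1.93 ± 0.36 SE, adjusted p = 0.00521), and 4.75% ± 0.0865 at 7 dpi (2.02, adjusted p = 0.00377). With the stricter cell filter these changes were 0.65 (adjusted p = 0.478) and 0.04 (adjusted p = 0.966), and that at 2 dpi had an adjusted p of 0.0684 without wild type 2 dpi replicate 2 and 0.0618 without wild type uninjured replicate 1. Endothelial-like cells were 53.2% ± 12.1 in uninjured wild type hearts, 23.2% ± 11.8 at 2 dpi and 24.8% ± 2.01 at 7 dpi (n = 2 each), and the change at 2 dpi did not pass the threshold (adjusted p = 0.109). Macrophage-like cells were 6.50% ± 6.01, 23.5% ± 21.4 and 18.8% ± 7.48 at these times, also without passing it at 2 dpi (1.85 ± 1.03, adjusted p = 0.174). With 1 library left out this change ranged from 0.36 to 3.39 and that at 7 dpi from 0.8 to 3.06. Without wild type 2 dpi replicate 1 the change of endothelial-like cells was past the threshold (-1.85, adjusted p = 0.0181), as it was without kit mutant 2 dpi replicate 2 (-1.21, adjusted p = 0.048). Over both genotypes the share of endothelial-like cells in injured minus uninjured libraries was -20.5 percentage points (exact two-sided permutation test, p = 0.0204, adjusted p = 0.138).

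Fibroblast- or epicardial-like cells were a smaller share in kit mutant, with a log2 difference of -0.65 ± 0.18 (SE, adjusted p = 0.0175), and their mean difference over time points was -7.20 percentage points (exact two-sided permutation test, p = 0.00617, adjusted p = 0.0445). Their mean share was lower in kit mutant at each of the 4 times, 9.14% against 18.8% in uninjured hearts, 16.5% against 20.8% at 2 dpi, 14.4% against 21.9% at 7 dpi and 14.0% against 21.3% at 14 dpi. The adjusted p of edgeR's test was 0.0606 without kit mutant 14 dpi replicate 2, 0.0518 without kit mutant 7 dpi replicate 1, 0.064 with the stricter cell filter, and 0.118 and 0.209 with the 3 kit mutant libraries grouped by their other labels or left out. Endothelial-like cells were 13.3 percentage points higher in kit mutant (exact two-sided permutation test, p = 0.0247, adjusted p = 0.0445), a difference that edgeR's test did not call (log2 0.52, adjusted p = 0.111) but did without kit mutant 2 dpi replicate 2 (0.62, adjusted p = 0.045) and without wild type 2 dpi replicate 1 (0.68, adjusted p = 0.0239). Cardiomyocyte-like cells, which centrifugation was meant to remove, were lower in kit mutant (-1.56, adjusted p = 0.0172) and erythrocyte-like cells higher (0.81, adjusted p = 0.0172), with adjusted p of 0.118 for each under the other grouping of the 3 kit mutant libraries. Thrombocyte-like cells were 0.71 percentage points higher in kit mutant (exact two-sided permutation test, p = 0.0154, adjusted p = 0.0445). The test of edgeR did not call that difference (log2 1.27, adjusted p = 0.0664). Macrophage-like cells showed no difference past the threshold, with 26.0% ± 16 in kit mutant and 23.5% ± 21.4 in wild type at 2 dpi (SD, n = 2 each). No class had a difference between genotypes that varied with time past the threshold.

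**Figure D3:**
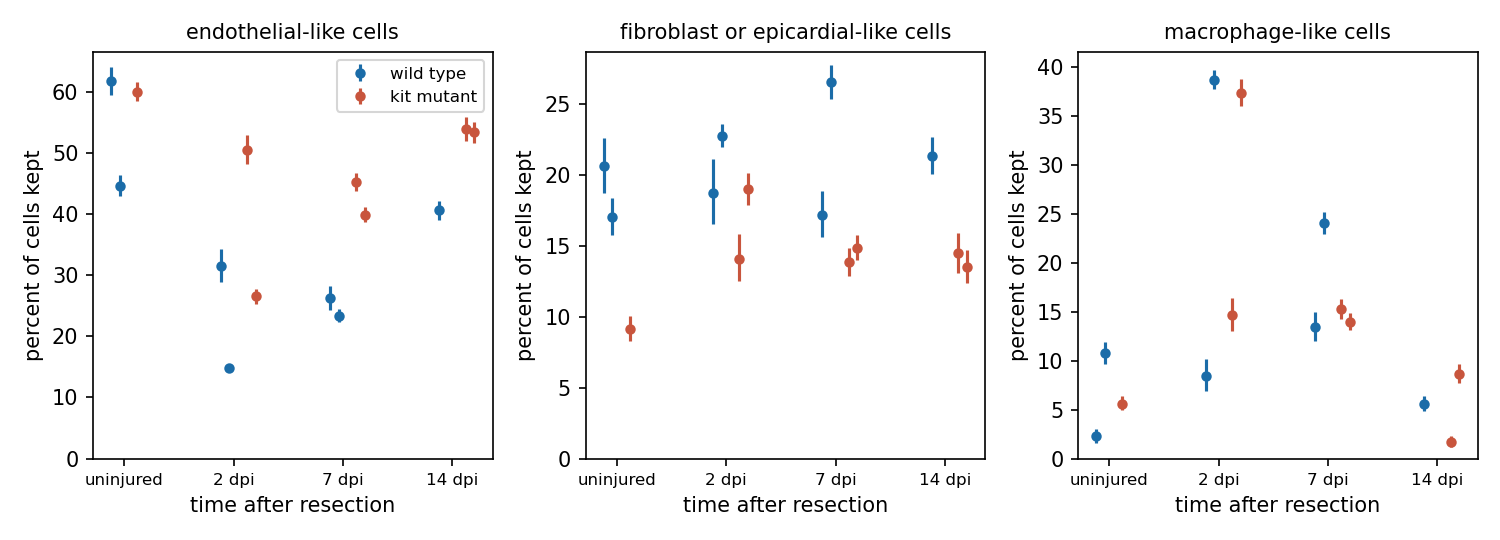
Share of all cells kept, in percent, of endothelial-like, fibroblast- or epicardial-like and macrophage-like cells against time after resection; each point is 1 library of wild type (blue) or kit mutant (red) with its exact 95% binomial interval. Mean shares of fibroblast- or epicardial-like cells were 18.8% in uninjured wild type and 9.14% in uninjured kit mutant.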

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

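The tests of free RNA, of a peculiarity of the wild type libraries, of a wrong label, of droplets with 2 cells, of the sets of libraries and of the size of the change that goes with mitochondrial share were chosen after the result was seen, while the splits of the samples, the chromosome test and the test of signs by mitochondrial share were not.

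Genes differed between kit mutant and wild type in 3 cell classes, 349 in endothelial-like, 260 in fibroblast- or epicardial-like and 54 in macrophage-like cells, and in each class 2 of 100 splits of genotype within time points, the real one included, called as many, which argues against chance alone. The highest other counts were 712, 322 and 146 in the same order, the first and the last from 1 split and that of fibroblast- or epicardial-like cells from another, and they point to a structure of the samples. Both splits set kit mutant 14 dpi replicate 2, 2 dpi replicate 2, 7 dpi replicates 1 and 2 and uninjured replicate 1 together with wild type 2 dpi replicate 2. The first adds wild type uninjured replicate 2 and called 24 genes in fibroblast- or epicardial-like cells, and the second adds wild type uninjured replicate 1 and called 110 in endothelial-like and 0 in macrophage-like cells. Where the first divides a group of 2 libraries it takes replicate 2, and the second does so except in uninjured wild type. The set found in each class (the first for macrophage-like cells) was entered as a covariate. Then 100%, 98.8% and 100% of the called genes kept their sign and at least 50% of their change. This cannot decide whether such a set is the whole source, because the genes had to be called first. Each set divides most groups of 2 libraries, and a gene that follows it varies within those groups, which hinders a call. Such a set may contribute: 221 of 349, 85 of 260 and 29 of 54 genes were called in both fits, and 7 of 29, 17 of 27 and 6 of 10 named genes lost their call. Genes whose call ended had a median absolute log2 change of 2.12 (median SE 0.46) before and 1.75 (0.51) after in endothelial-like, 1.9 (0.4) and 1.54 (0.44) in fibroblast- or epicardial-like and 2.89 (0.54) and 2.2 (0.54) in macrophage-like cells, so their changes became smaller, and the covariate takes a degree of freedom. Free RNA of macrophages in wild type droplets is argued against as the whole source of the genes lower in kit mutant, because 69.2% of those in endothelial-like and 61.9% of those in fibroblast- or epicardial-like cells had a higher level in their own class than in macrophage-like cells. Stretches of chromosome from another strain, carried by 1 genotype, may contribute. Called genes with a known position (67.1% of them) lay near another called gene 1.48 times as often as random sets. Genes called at 2 dpi gave 1.06. The central 95% of 2000 random sets ended at 1.36, and the highest had 77 such genes against 72 observed. Of tested genes within 50 positions, 7 of 67 were called around kita and 4 of 52 around kitb, against 2.85% in all. This difference was not tested. No chromosome passed the threshold (Fisher's exact test, lowest adjusted p = 0.815). The longest run held 6 genes of chromosome 13, and all of them but si:dkey-188i13.10 were called in all 3 classes. Runs of genes with related names, such as 4 of ms4a17a, raise the measure too. The called genes without a position could not be searched. In the 3 classes 46.4%, 36.2% and 64.8% of the called genes had only a clone or database identifier, against 19.6%, 16.6% and 14.7% of those tested. Of genes called at 2 dpi in fibroblast- or epicardial-like cells 11.9% did. Of the genes called for genotype 13, 10 and 6 had no UMI in any kit mutant library, and 1, 0 and 0 had none in any wild type library. Where this comes from was not tested. An effect of the kit alleles on these cells, the biological difference that the design names, stays open and untested.

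In fibroblast- or epicardial-like cells of wild type 495 genes were called at 2 dpi, among them col12a1a, timp2b and mdka. A peculiarity of the 4 wild type libraries is argued against, because 99.2% of these genes had the same sign in kit mutant at 2 dpi against uninjured, where 75% of all genes did. The values of these kit mutant libraries do not enter the wild type change, though they enter the estimate of spread that decides which genes are called. Free RNA of macrophages is argued against as the whole source of the genes that rose, since 86.4% of them had a higher level in this class than in macrophage-like cells at 2 dpi. Between libraries of low and of high mitochondrial share in 3 other groups the called genes had a median log2 change of 0.36. It was in the direction of the wild type change, and 2.21 would be needed at that gap in mitochondrial share. The 95% interval of 0.33 to 0.39 treats genes as independent and leaves out the spread between libraries. This value cannot decide whether the higher mitochondrial share of the uninjured libraries is the whole source. The 3 groups enter the estimate of spread, so genes that differ within them are hard to call. As the whole source the mitochondrial share is argued against by a single comparison of libraries. In kit mutant 2 dpi replicate 2 these genes were changed in that direction by a median of 1.95 from the uninjured kit mutant library, although its mitochondrial share was higher (9.61% against 5.77%). The mitochondrial share may contribute: over the 3 groups together 79.6% of the called genes had the same sign as in wild type, against 65.1% of all genes, and in the single groups 72.5%, 71.3% and 60.6% did. A response of these cells to the resection, which the design names, also stays open.

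Cells of cluster 22, which carried no class name and entered no comparison, were 10.2% of cells in kit mutant uninjured replicate 1 (418 cells, exact 95% interval 9.283% to 11.159%), 0.917% in kit mutant 2 dpi replicate 1 and 0.635% in kit mutant 14 dpi replicate 2, all above the highest upper bound of the uninjured wild type libraries (0.224%). The same kit mutant uninjured library had 4.07% neutrophil-like cells. A 2 dpi library with the wrong label is argued against, because the genes called at 2 dpi in fibroblast- or epicardial-like cells lay there at 8.4% of the way from uninjured to 2 dpi wild type, where kit mutant 2 dpi replicates lay at 101.3% and 80.9%. A 7 or 14 dpi library with the wrong label cannot be told apart from an uninjured one on this scale, since the lowest of those libraries lay at 8.5%. Cluster 10 held none of the 375 fibroblast- or epicardial-like cells of kit mutant uninjured replicate 1, and 0.1% of the class in uninjured wild type. In the 7 and 14 dpi groups it held 6.4% to 14.6%, which goes against such a wrong label. These shares pool the libraries of a group, so their spread between libraries is not known here. Droplets with 2 cells may contribute and cannot be told apart from a true cell state. In kit mutant uninjured replicate 1 the cells of cluster 22 had a median of 3892.5 UMIs, against 2940.5 in its macrophage-like and 3345 in its neutrophil-like cells. Its cells that passed the filters, however, had a median of 3829 UMIs before doublets were removed. The assumed rate gave 144 doublets in this library, fewer than the 418 cells of cluster 22. Over all libraries together 2.5% of the cells of cluster 22 were scored as doublets, against 4.4% of all cells. The uninjured kit mutant group holds 1 library, so whether the genotype brings these cells was not tested.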

How the results depend on the processing

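The mitochondrial limit of 40% and the covariates for sets of libraries were chosen after seeing the data; the other alternatives were planned. Counts of called genes were within 1.5 times the first value, or 0 in both, in 165 of 225 results under alternatives other than leaving out 1 library and in 213 of 260 with 1 library left out. Named genes kept their direction and side of the threshold in 1624 of 1899 and 1582 of 2127 results, and 5 and 9 reversed, all of them kitlga. Single gene lists kept theirs in 268 of 408 and 1089 of 1255. The cause of the changes below was not tested, except that the covariates and the block take degrees of freedom and the fits without a library have fewer samples.

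Counts of called genes, in the order wild type 2, 7 and 14 dpi, genotype and interaction where they moved, were as follows. DESeq2 gave 42, 4, 688 (genotype) and 8 (interaction) in endothelial-like, 854, 53, 2, 397 and 3 in fibroblast- or epicardial-like, 52 and 164 (genotype) in macrophage-like, and 6, 3 and 184 (genotype) in cardiomyocyte-like cells. Without a filter on low counts they were 88, 36, 12, 1157 and 38, then 1111, 125, 51, 755 and 23, then 85, 13, 1, 284 and 5, then 58, 30, 32, 343 and 15 in the same classes. With groups by the other labels fibroblast- or epicardial-like cells gave 0, 0 and 111 (genotype), macrophage-like cells 0 at 2 dpi and cardiomyocyte-like cells 122 for genotype. With the set as a covariate fibroblast- or epicardial-like cells gave 1185, 35, 1 and 168, macrophage-like cells 36 at 2 dpi and cardiomyocyte-like cells 1 at 7 dpi. With the second set fibroblast- or epicardial-like cells gave 1115 at 2 dpi and 98 for genotype. At 7 dpi fibroblast- or epicardial-like cells gave 4 with the looser mitochondrial limit, 7 with Leiden resolution 0.5, 7 with doublets kept and 2 without the 3 libraries, where cardiomyocyte-like cells gave 20 for genotype. The replicate numbers of the labels were checked for pairing by the correlation of deviations from group means, before calls were compared: 8, 7 and 13 of 15 pairs of groups exceeded 0.1 in endothelial-like, fibroblast- or epicardial-like and macrophage-like cells, the lowest being -0.217. The 3 pairs of wild type groups all exceeded it, with 0.202 to 0.421, and replicate 1 had fewer barcodes than replicate 2 in all 6 groups of 2 libraries. As the pairs with kit mutant groups did not all exceed it, the numbers were not taken to pair libraries. In each group of 2 libraries that the first set divides, however, the set holds replicate 2 and leaves out replicate 1. The set and the numbers therefore overlap, and a difference in handling between the replicates cannot be told apart from the set there. As a block the replicate numbers gave 581 in endothelial-like cells for genotype and 831, 23 and 400 (genotype) in fibroblast- or epicardial-like cells. They gave 49 and 271 in macrophage-like and 4 and 151 in cardiomyocyte-like cells at 2 dpi and for genotype.

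With 1 library left out the counts ranged from 0 to 5 (2 dpi) and 134 to 498 (genotype) in endothelial-like cells, from 44 to 845, 0 to 16, 114 to 367 and 0 to 2 (2 dpi, 7 dpi, genotype, interaction) in fibroblast- or epicardial-like cells, from 0 to 21 and 20 to 72 (2 dpi, genotype) in macrophage-like cells, and from 0 to 2, 0 to 2 and 31 to 121 (2 dpi, 7 dpi, genotype) in cardiomyocyte-like cells. The genotype comparisons could not be fitted without either library that stands alone in its group.

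Of 19 lists, an estimated correlation left 0 in every comparison but cardiomyocyte-like cells at 7 dpi (1). Groups by the other labels gave 3 for genotype in endothelial-like and 1 (14 dpi) and 2 (genotype) in macrophage-like cells, and the block 1 there at 14 dpi. The set as a covariate gave 10 (14 dpi) and 2 (genotype) in endothelial-like, 5 (genotype) in fibroblast- or epicardial-like, 3 (7 dpi) and 2 (genotype) in macrophage-like and 3 (14 dpi) in cardiomyocyte-like cells, and it reversed cell cycle genes in endothelial-like (adjusted p = 0.553) and fibrillar matrix genes in cardiomyocyte-like cells (adjusted p = 0.353) for genotype. The second set gave 4 for genotype in fibroblast- or epicardial-like cells and reversed basement membrane genes there (adjusted p = 0.802). With 1 library left out list counts ranged, for 2, 7 and 14 dpi and genotype, over 7 to 13, 5 to 10, 4 to 8 and 3 to 10 in endothelial-like, 4 to 8 at 14 dpi in fibroblast- or epicardial-like, 3 to 9, 0 to 4 and 0 to 3 (2 dpi, 7 dpi, genotype) in macrophage-like and 3 to 7, 2 to 8 and 1 to 5 (7 dpi, 14 dpi, genotype) in cardiomyocyte-like cells. Lists that reversed in some of these fits had adjusted p from 1.37e-11 to 0.723 and 1.84e-17 to 0.435 (immediate early genes, endothelial-like, 2 and 7 dpi), 0.000141 to 0.868 (the same list, fibroblast- or epicardial-like, 14 dpi), 1.22e-05 to 0.635 (cell cycle, macrophage-like, 2 dpi) and 1.34e-07 to 0.433 (interferon response, cardiomyocyte-like, 7 dpi).

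Log2 changes of shares with the set as a covariate were -1.27 (2 dpi), -1.40 (7 dpi) and 0.85 (genotype) for endothelial-like and 1.87, 2.93, 1.18 and -1.09 (2, 7, 14 dpi, genotype) for macrophage-like cells, and with the block -1.25, -1.07 and 0.54, and 1.86, 1.83 and 0.84. Endothelial-like cells gave 0.61 for genotype with the looser mitochondrial limit. Fibroblast- or epicardial-like cells gave -0.57, -0.60 and -0.62 for genotype with groups by the other labels, without the 3 libraries and with the stricter cell filter, and macrophage-like cells 0.04 and 0.16 under the first 2 of these. With 1 library left out the ranges were -1.85 to -0.76 (endothelial-like, 2 dpi), 0.39 to 0.68 (genotype), -0.01 to 0.28, -0.13 to 0.50 and -0.72 to -0.56 (fibroblast- or epicardial-like, 2 dpi, 7 dpi, genotype), and -0.95 to 1.30 and -0.54 to 0.25 (macrophage-like, 14 dpi, genotype).

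The kitlga value in endothelial-like cells, not called in any fit, was -0.85 and -0.64 at 2 and 7 dpi with Leiden resolution 0.5, 0.35 (14 dpi) and -0.40 (genotype) with the set as a covariate and 0.30 (14 dpi) with the block. Left-out libraries gave -0.49 to 0.66, -0.35 to 0.16 and -0.19 to 0.19 there (2 dpi, 14 dpi, genotype), and -2.12 to 5.72 and -0.78 to 1.22 in macrophage-like cells (14 dpi, genotype).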

Other observations

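The tests of this part are those of the comparisons above and were planned, except that the scale from uninjured to 2 dpi was chosen after the result was seen. The genes called in cardiomyocyte-like cells were named by the same rule as the others.

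Cardiomyocyte-like cells that remained after centrifugation were fitted as a further class, with 8620 genes. The comparison of genotypes called 64 genes, 29 of them higher in kit mutant. The small nuclear RNA gene rn7sk was 11.4-fold higher in kit mutant (log2 3.51 ± 0.42 SE, adjusted p = 0.00129, 7 libraries against 7) and the creatine transporter gene slc6a8 5.95-fold (adjusted p = 0.00951). The heart protein gene lrrc10 fell by 3.74 ± 0.44 (log2, adjusted p = 0.00129), ptgr1, which encodes a prostaglandin reductase, was 6.07-fold lower (adjusted p = 0.00559) and cish, which encodes a suppressor of cytokine signalling, 3.80-fold lower (adjusted p = 0.0138). Each of these genes differed with the same sign at all 4 time points. Interferon response genes had 2 of 16 lower and 9 adjusted over the list alone (median -2.95, camera adjusted p = 1.41e-07; adjusted p = 0.749 with an estimated correlation). Fibroblast or epicardial markers had a median of -0.97 (0 of 12 called), macrophage markers of -0.74 (0 of 10 called) and T or NK markers of -1.42 (0 of 4 called). The count was 41, 36, 33 and 31 without kit mutant 14 dpi replicate 2, kit mutant 2 dpi replicate 1, wild type 7 dpi replicate 1 and wild type uninjured replicate 2, and 121 without wild type 2 dpi replicate 2. Without the 3 kit mutant libraries whose labels differ it was 20, and cish had an adjusted p of 0.0963.

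In wild type, cardiomyocyte-like cells had 0 called genes at 2, 7 and 14 dpi by edgeR, with 270, 192 and 204 at an unadjusted p under 0.05, while DESeq2 called 6, 3 and 0. Cell cycle genes had a median log2 change of 2.1, or 1.64 with bounds, at 7 dpi in these cells, with 2 of 23 higher adjusted over the list alone (camera adjusted p = 4.77e-14), and this call held with an estimated correlation (adjusted p = 0.0212). Markers of other cells moved too, macrophage markers with a median of 1.45 (0.13 to 6.92, 0 of 10 called), erythrocyte markers of 1.37 (0.01 to 1.85, 0 of 9 called) and endothelial markers of -0.92 (-2.67 to -0.28, 0 of 9 called). At 14 dpi interferon response genes had a median of 1.83, or 1.55 with bounds (camera adjusted p = 6.25e-07; adjusted p = 0.583 with an estimated correlation), with 0 of 16 past the threshold, while fibroblast or epicardial markers had a median of -1.9 (0 of 12 called) and endothelial markers of -1.19 (0 of 9 called).

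On the scale from uninjured to 2 dpi wild type, set by the 495 genes called in fibroblast- or epicardial-like cells, kit mutant 2 dpi replicates 1 and 2 lay at 101.3% and 80.9%, kit mutant 7 dpi replicates 1 and 2 at 28.4% and 20.9%, and kit mutant 14 dpi replicates 1 and 2 at 17.6% and 8.5%. The wild type libraries at 7 dpi lay at 45.2% and 30.8% and that at 14 dpi at 20.0%. No library was regrouped by these values.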
